A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

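RNA of budding yeast, Saccharomyces cerevisiae, was measured on 7 one-colour Affymetrix arrays that carry probe sets for this species and for the fission yeast Schizosaccharomyces pombe. The arrays held wild type cells kept at 25C (1 array) and wild type, scc2-4 and sth1-3 cells shifted to 37C for 2 h (2 arrays each), all grown in rich medium with 2% glucose from an OD600 of 0.25, per the labels. The deposited values are log2 intensities, 1 per probe set and array. The submitters' processing notes name RMA and the affy package, without versions. RMA corrects the background, makes the distributions of the arrays equal by quantile normalization and summarises the probes of a set. The labels do not say whether all 7 arrays were normalized together, and separate runs could add to differences between the array sets described in the report. The values lay between 4.97 and 14.7 and were used as deposited. Scanner files were not used here, so RNA quality, scan date and probe-level background were not examined.

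Of the 10928 probe sets, 7244 had 1 gene symbol in the platform annotation, 1 had several and 3683 were unnamed here. Those with 1 symbol comprised 5498 for S. cerevisiae and 1746 for S. pombe, told apart by whether the gene identifier was among the S. cerevisiae R64 reference genes. Symbols were updated through the same reference, which changed 12 of them, and no coordinates were used. A gene with several probe sets was represented by the brightest on average, which left 5449 genes. In 18 of the 47 genes with several probe sets, the lowest correlation between a pair of them over the arrays was under 0.5. The 95th percentile of the S. pombe probe sets on each array served as background. A gene not above it on any array of a group has only a bound there. Folds against such a group are then given as "at least", from the higher of the background and the gene's own value on each array, and no fold is given where neither group rose above background.

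Groups were taken from the sample titles. The growth protocol of the wild type 25C sample, worded as for all others, describes the shift to 37C, so its temperature rests on its title, source name and description. The design text of the series speaks of each strain at both temperatures, while the titles of all mutant arrays give 37C. All 7 arrays were fitted in 1 linear model with a mean per group, using lmFit and eBayes of limma 3.58.1 in R 4.3.3, which left 3 residual degrees of freedom. The 4 comparisons were two-sided, with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05. In this text, an adjusted p of a gene comes from limma. The 38 gene lists, with 984 of 1021 members measured, were tested with limma's camera at a preset inter-gene correlation of 0.01, again two-sided and adjusted over the lists. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. No pair of arrays held identical values. With 1 or 2 arrays per group, the number of arrays limits the precision of every value.

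The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named, among called genes above background with no overlap between groups, those with the largest changes, and called members of called lists. Where fewer than 5 genes were called, which was so in all 4 comparisons, it named the 10 genes with the smallest p, as not past the threshold. It always named SCC2, SCC4, STH1, URA3, TRP1 and the a-specific and alpha-specific genes. No probe set for TRP1 or MATALPHA1 was named here. The rule of naming the 3 brightest members of a list as examples, the genes PMA1 and YER138W-A, and a list of 8 Ty1 and Ty2 open reading frames, with 4 of Ty3 and Ty4 beside it, were chosen after values were seen.

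Alternatives were a replicate block, eBayes with a trend or with robust hyperparameters, a filter on dim genes, 3 other normalizations, the mean of all probe sets of a gene, leaving out probe sets marked as shared, fitting only the groups compared, and leaving out each 37C replicate in turn. For the lists, camera with an estimated correlation and fry were added. After the data were seen, 2 further fits were made because the bacterial hybridisation controls split the arrays into sets of 3 and 4. One adds the array set as a term (2 residual degrees of freedom). The other uses only the 4-array set, where each mutant has 1 array that is assumed to vary like the wild type pair (1 residual degree of freedom). eBayes estimated 5.26 prior degrees of freedom without the term, 105 with it, and an infinite number within the 4-array set. It was infinite too where only the wild type arrays were fitted. These fits therefore give nearly all genes 1 common spread, and their p-values are too small for genes that vary more than others.

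The procedure was tested on simulated data for the comparison of scc2-4 with wild type over the 5449 genes, in 20 draws that each changed 100 genes by 1 and 100 genes by 2 on the log2 scale. Gene variances were drawn from the variance model that limma fitted to the arrays. A first version that took each gene's own shrunken variance gave a larger share of false calls, and the noise model was replaced after that outcome was seen. Of genes changed by 2, 26.4% were called, and of genes changed by 1, 0.9%. With the set term these shares were 96.6% and 24.5%. Noise for each model came from its own fit, without an array set effect, so the shares do not show a gain from the term. False calls made up 5.21% and 5.13% of all calls. Since the noise followed limma's own variance model, these false shares do not test whether that model holds on the arrays. A shift of 0.5 in the ribosomal protein genes was called by camera in 20 of 20 draws. The simulated genes vary independently, unlike those on the arrays.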

Results

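Transcript levels were compared in budding yeast cells that lost the function of Scc2 or of Sth1. Scc2 is a subunit of the complex that loads cohesin onto chromosomes, and Sth1 is the ATPase of the nucleosome remodeller RSC. The scc2-4 and sth1-3 strains carry temperature-sensitive alleles, and their cells, like those of a wild type strain, were shifted to 37C for 2 h before RNA was taken. There were 2 arrays each for wild type, scc2-4 and sth1-3 at 37C, and 1 array for wild type at 25C. The scc2-4 strain also carried tagged Scc1 and Sth1, the sth1-3 strain carried tagged Scc2 and was of mating type alpha, and the other strains were of mating type a. The comparisons ask which transcripts depend on either protein at 37C, how alike the 2 mutants are, and what the shift itself does in wild type cells.

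Signal over background was low. Between 439 and 705 of the 5449 S. cerevisiae genes lay above the 95th percentile of the S. pombe probe sets of their array, a share of 8.06% to 12.9%. Across arrays, 905 genes passed this level on at least 2 arrays and 4219 on none. The median S. cerevisiae gene lay at 8.56 to 8.79, and the median S. pombe probe set at 8.33 to 8.54.

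The arrays fell into 2 sets that did not follow the groups. The bacterial hybridisation controls averaged 12.6 on the wild type 25C array, 12.5 on scc2-4 replicate 1 and 12.3 on sth1-3 replicate 1, called the 3-array set here. They averaged 11.8 and 11.7 on the wild type 37C arrays and 11.6 on replicate 2 of either mutant, the 4-array set. The 3' probe set of the 25S ribosomal RNA exceeded its 5' probe set by 3.03 to 4.16 in the 3-array set and by 0.30 to 0.69 in the 4-array set. The 5.8S ribosomal RNA probe set lay at 7.50 to 8.40 in the 3-array set and at 12.87 to 12.98 in the 4-array set, except for 8.92 on sth1-3 replicate 2. Across S. cerevisiae genes, arrays of the same set correlated at r = 0.85 to 0.98 and arrays of different sets at 0.67 to 0.86. The replicates of wild type at 37C, both in the 4-array set, correlated at 0.92, whereas those of scc2-4 and sth1-3, split between the sets, correlated at 0.79 and 0.76. Replicates differed by more than 1 log2 unit in 164 genes in wild type, 775 in scc2-4 and 1057 in sth1-3. Wild type at 25C was represented only in the 3-array set and wild type at 37C only in the 4-array set.

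**Figure D1:**
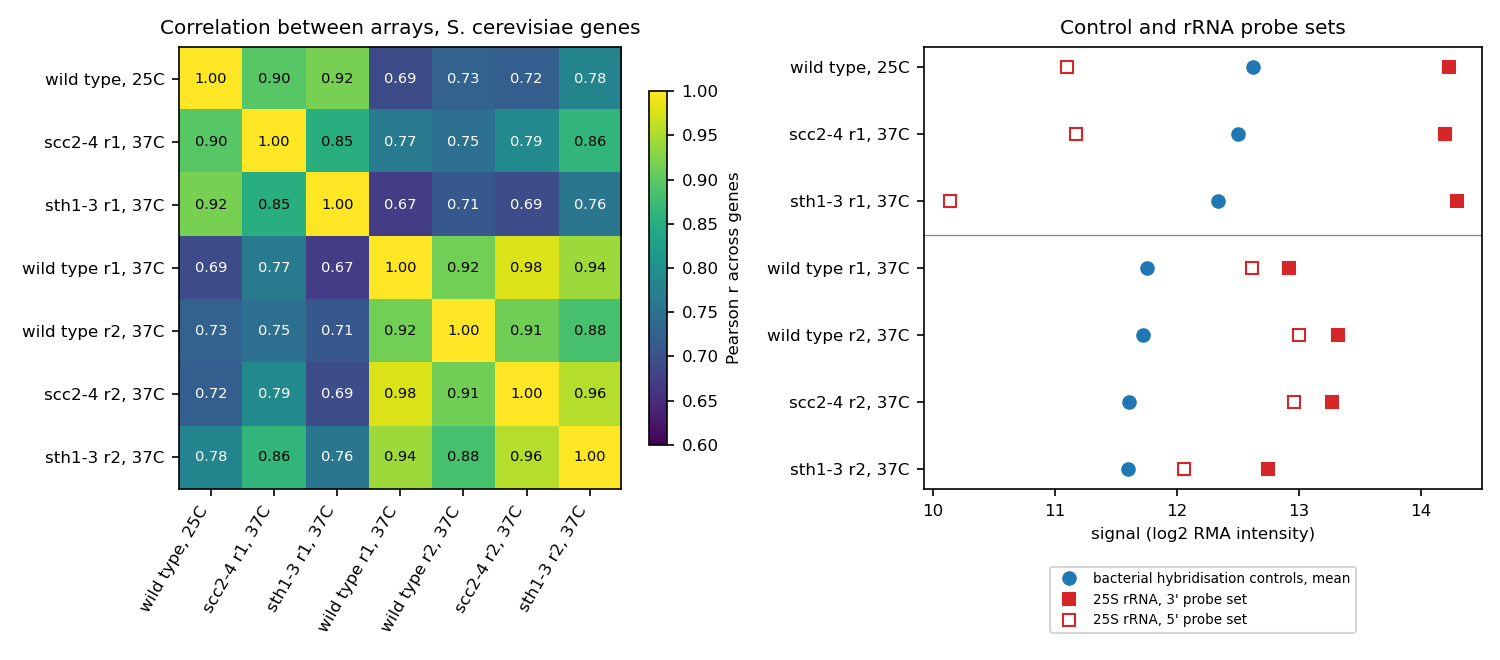
Left, Pearson r across 5449 S. cerevisiae genes for each pair of the 7 arrays (r1 and r2 are replicates); right, signal in log2 units of the bacterial hybridisation controls and of the 3' and 5' probe sets of 25S ribosomal RNA on each array, 1 point per array. The 3 arrays above the line correlate at 0.85 to 0.92 with each other, have higher hybridisation controls and a wider gap between the 3' and 5' probe sets than the 4 below it.

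The genes that could check the strains gave little signal. SCC2 was not above background on any array (7.19 ± 0.05 in scc2-4, 7.58 ± 0.11 in sth1-3 and 7.50 ± 0.35 in wild type at 37C, log2 signal, SD, n = 2 each). STH1 was not above background either (9.33 ± 0.28 in scc2-4, 8.90 ± 0.22 in sth1-3 and 9.52 ± 0.25 in wild type). The alleles change the proteins, so transcript levels of either gene do not check the labels. SCC4, which encodes the partner of Scc2, was above background on every array. It measured 11.08 ± 0.63 in scc2-4, 11.14 ± 0.60 in sth1-3, 10.34 ± 0.24 in wild type at 37C and 11.07 on the wild type 25C array. These values followed the array sets, at 11.07 to 11.56 in the 3-array set and 10.17 to 10.72 in the 4-array set. SCC4 was not called against wild type at 37C in scc2-4 or sth1-3 (adjusted p = 0.998 and 0.824, limma). URA3, a marker in the scc2-4 strain, was not above background (8.30 ± 0.78 there and 7.89 ± 0.16 in wild type at 37C). The mating type genes could not tell the alpha strain from the a strains. All 7 a-specific genes (STE2, MFA1, MFA2, BAR1, STE6, AGA2 and ASG7) and 5 of the alpha-specific genes (STE3, MF(ALPHA)1, MF(ALPHA)2, SAG1 and AFB1) were not above background on any array, and HMLALPHA1 was above it on 1 sth1-3 array. MF(ALPHA)1, the main gene of the alpha pheromone, measured 9.36 ± 0.31 in sth1-3 and 7.98 ± 1.11 in scc2-4 (adjusted p = 1.00).

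In scc2-4 against wild type at 37C, the genes with the smallest p were mostly open reading frames of Ty1 and Ty2 retrotransposons, higher in the mutant. They made up 7 of the 10, and none passed the threshold (adjusted p = 0.998 for each of the 10, limma). YBL100W-A measured 10.79 ± 0.40 in scc2-4 and 8.43 ± 0.66 in wild type (SD, n = 2), at least 1.69-fold higher. YDR261C-D measured 10.88 ± 1.12 and 7.49 ± 0.99, at least 1.80-fold. YDR261W-B (at least 1.84-fold), YBL100W-B (at least 1.16-fold), YAR009C (at least 2.29-fold) and YDR316W-B (10.61 ± 1.95 against 7.74 ± 0.72) were likewise not above background on either wild type array. In scc2-4, YDR261W-B (SD 1.45), YBL100W-B (SD 2.31) and YDR316W-B were above background only on replicate 1, so their bounds rest on that array. YAR010C, above background on 1 of them, was 3.73-fold higher (12.29 ± 0.34 against 10.39 ± 0.64). Each of these probe sets is shared between near-identical Ty copies, so the values belong to no single locus. The other 3 genes were KRE6, which acts in synthesis of cell wall beta-glucan (9.75 ± 0.60 against 8.24 ± 0.39), SPO7, a subunit of a nuclear envelope phosphatase (7.24 ± 0.42 against 8.50 ± 0.58, neither above background), and CAT8, an activator of gluconeogenic genes (8.77 ± 0.17 against 10.14 ± 0.46, at least 1.13-fold lower). Over all genes, 0 were called by limma. At an unadjusted p under 0.05 there were 68 genes, 49 higher and 19 lower, and 152 with the array set as a term, where chance alone gives 272. Without the term eBayes with a trend or with robust hyperparameters also called 0. The arrays of the groups did not overlap in 1590 genes (29.2%), against 33.3% by chance for exchangeable arrays, a value that ignores the array sets.

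Among the 38 gene lists, 7 were higher and 3 lower in scc2-4 with camera's preset correlation. Cytosolic ribosomal protein genes had a median log2 change of 0.76, with 119 of 127 members higher (adjusted p = 4.4e-21). Its brightest members were RPS8A (11.21 ± 0.07 against 10.71 ± 0.66), RPL24B (10.72 ± 0.89 against 10.18 ± 0.09) and RPS11A (10.91 ± 0.30 against 10.59 ± 0.20). Glycolysis and fermentation genes had a median of 0.99, with 16 of 16 higher (adjusted p = 5.0e-07). TDH3, a glyceraldehyde-3-phosphate dehydrogenase, measured 11.42 ± 1.43 against 10.25 ± 0.04, and ENO2, an enolase, 11.27 ± 1.45 against 10.02 ± 0.05. The other higher lists were ribosome biogenesis (0.11), cell wall (0.26), proteasome (0.24), Hsf1 chaperones (0.22) and unfolded protein response (0.48). Seripauperins, small cell wall proteins of anaerobic cells, were lower (-0.51, 18 of 19 members, adjusted p = 6.6e-05), with PAU23 at 13.07 ± 1.23 against 14.20 ± 0.01. Early meiosis (-0.31) and G1/S genes (-0.29) were the other lower lists. No list member was called, over all genes or adjusted over the list alone. With an estimated correlation no list was called (lowest adjusted p = 0.679), nor with fry (lowest adjusted p = 0.713). On the wild type 37C arrays only 9 and 11 of the 127 ribosomal protein genes and 2 and 1 of the 16 glycolysis genes were above background. With only genes above background on at least 2 arrays, 3 lists were called higher and 1 lower at the preset correlation.

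These list changes moved with the array set. Relative to the wild type 37C mean, the ribosomal protein list had a median of 1.41 on scc2-4 replicate 1 and 0.06 on replicate 2, and 1.53 on the wild type 25C array. For glycolysis the values were 1.87, 0.10 and 1.81, and for seripauperins -1.10, -0.022 and -1.07. The other higher lists lay at -0.065 (unfolded protein response) to 0.087 (Hsf1 chaperones) on replicate 2, early meiosis at -0.13 and G1/S genes at -0.12. Alpha-specific genes, not among the lists called over all arrays, lay at -0.44 on replicate 2, with none above background on that array. They were the list called lower within the 4-array set, in a fit with 1 scc2-4 array. With the array set as a term, chosen after the data were seen, no list was called (lowest adjusted p = 0.0753). The same term gave 7 genes higher and 0 lower, all 7 of them Ty1 and Ty2 reading frames, and within the 4-array set 6 of these were called and no other gene.

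**Figure D2:**
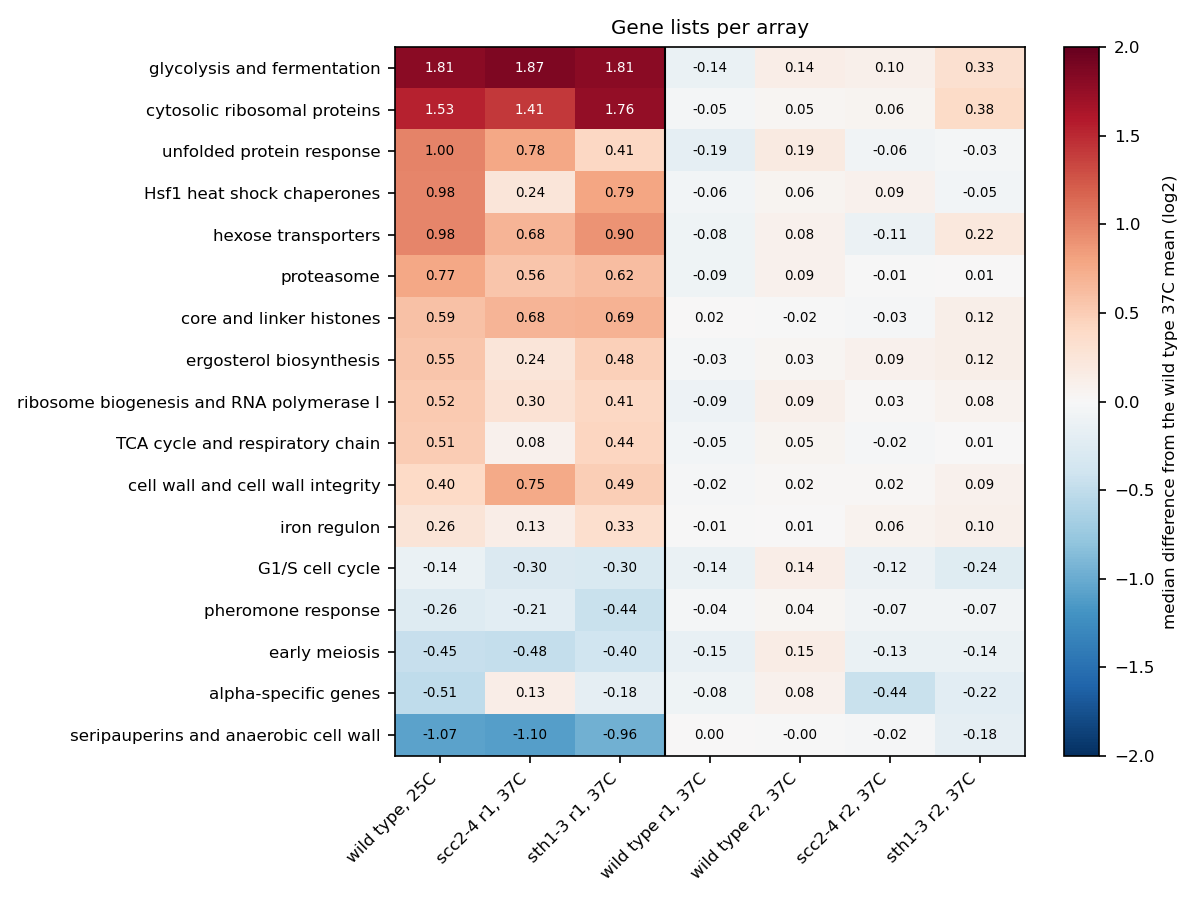
Median difference of each gene list from the mean of the wild type 37C arrays, in log2 units, on each of the 7 arrays (columns; r1 and r2 are replicates), for the lists called in any comparison. Columns left of the line are the 3-array set; glycolysis lies at 1.81 to 1.87 there and at -0.14 to 0.33 in the 4-array set.

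In sth1-3 against wild type at 37C, Ty1 and Ty2 reading frames again led the genes with the smallest p, as 6 of the 10, and none passed the threshold (adjusted p = 0.824 for each of the 10). YDR261W-B measured 11.35 ± 0.42 in sth1-3 and 7.85 ± 0.50 in wild type, where it was not above background. YBL100W-A (at least 1.89-fold), YDR261C-D (at least 1.68-fold), YBL100W-B (at least 1.04-fold) and YDR316W-B (at least 1.90-fold) were also not above background on the wild type arrays, and YAR010C was 3.74-fold higher (12.29 ± 0.25 against 10.39 ± 0.64). YLR154C-H, a reading frame in the ribosomal DNA region, measured 9.24 ± 0.30 in sth1-3 and 11.82 ± 0.20 in wild type, at least 3.49-fold lower. The 5.8S ribosomal RNA was low on the same arrays, at 8.92 or less against 12.87 and 12.92. It was also low on the wild type 25C array (8.40), where YLR154C-H measured 11.52. The others were HEM12 of haem synthesis (9.31 ± 0.36 against 7.50 ± 0.25) and RBA50, an RNA polymerase II assembly factor (8.42 ± 0.33 against 9.70 ± 0.14), neither above background in either group, and YGP1, a cell wall glycoprotein (9.96 ± 0.32 against 8.77 ± 0.25). Over all genes 0 were called by limma. At an unadjusted p under 0.05 there were 206 genes, 112 higher and 94 lower, and 178 with the set term, against 272 by chance. Without the term eBayes with a trend or robust hyperparameters called 0. The arrays did not overlap in 2005 genes (36.8%), against 33.3% by chance, which again ignores the array sets.

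With the preset correlation 10 lists were higher and 4 lower in sth1-3. Ribosomal protein genes had a median of 1.08 (123 of 127 higher, adjusted p = 1.8e-24), with RPL24B at 11.27 ± 0.89 against 10.18 ± 0.09. Glycolysis genes had a median of 1.03 (16 of 16 higher, adjusted p = 9.4e-06), with ADH1, the fermentative alcohol dehydrogenase, at 11.02 ± 1.52 against 8.95 ± 0.21, at least 2.00-fold. On sth1-3 replicate 2 ADH1 was not above background (9.95 against 10.01), so this bound rests on replicate 1 (12.10). Histone genes (0.57, 8 of 9 higher), hexose transporters (0.52, 11 of 14), ergosterol synthesis (0.49, 20 of 25), proteasome (0.30), cell wall (0.31), ribosome biogenesis (0.28), iron regulon (0.20) and respiratory genes (0.20) were the other higher lists. Seripauperins (-0.60, 16 of 19 lower, adjusted p = 0.00247), pheromone response (-0.32), early meiosis (-0.29) and G1/S genes (-0.22) were lower. No member was called, over all genes or adjusted over the list alone, and with an estimated correlation no list was called (lowest adjusted p = 0.690). The array set moved with these lists too: the ribosomal protein median was 1.76 on sth1-3 replicate 1 and 0.38 on replicate 2. On replicate 2 the medians of the 8 other higher lists were 0.22 for hexose transporters, 0.12 for histones and for ergosterol synthesis, 0.10 for the iron regulon, 0.089 for cell wall, 0.077 for ribosome biogenesis, 0.011 for proteasome and 0.0099 for respiratory genes. The lower lists there were at -0.18 (seripauperins), -0.074 (pheromone response), -0.14 (early meiosis) and -0.24 (G1/S). With the set term the ribosomal protein (median 0.33, adjusted p = 1.4e-17) and glycolysis lists (0.40, adjusted p = 0.00194) were among 7 called, all higher, and with an estimated correlation none was (lowest adjusted p = 0.277). That term called 9 genes higher and 1 lower, of which 7 were Ty1 and Ty2 reading frames. The other 3 were YLR154C-H, the lower one, and 2 genes chosen after their values were seen, PMA1, the plasma membrane proton pump, at 11.22 ± 0.81 against 8.97 ± 1.00, and YER138W-A at 10.22 ± 2.51 against 5.97 ± 0.01.

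**Figure D3:**
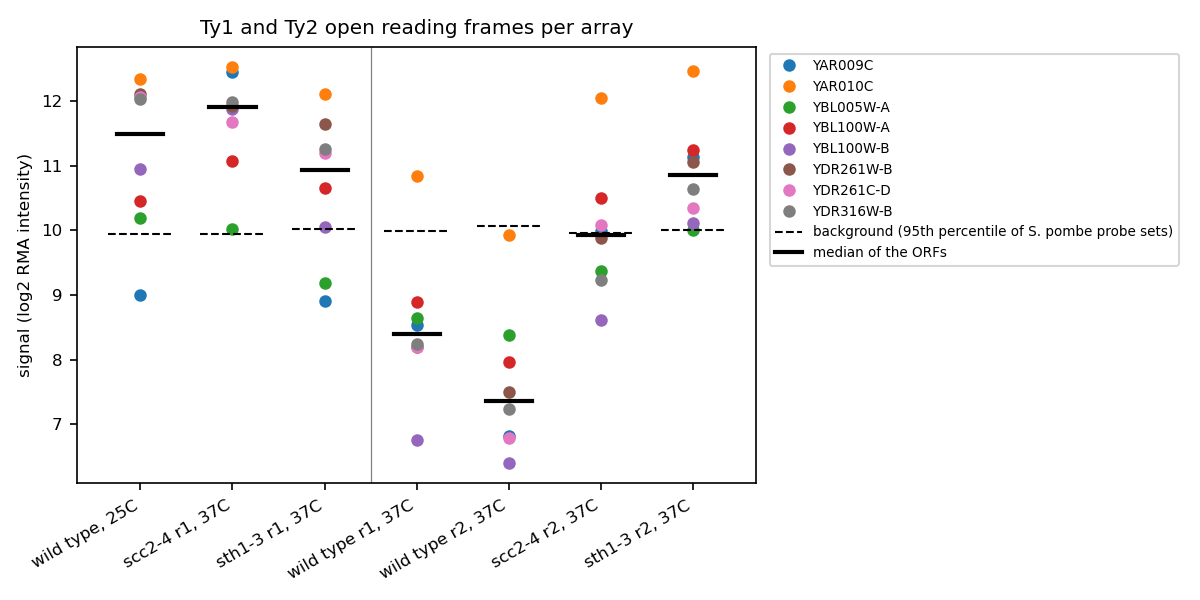
Signal in log2 units of 8 Ty1 and Ty2 open reading frames on each of the 7 arrays (r1 and r2 are replicates), with their median as a solid bar and the background of each array as a dashed bar; arrays left of the grey line are the 3-array set. The medians are 8.39 and 7.36 on the wild type 37C arrays, and 9.93 to 11.9 on the others.

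In sth1-3 against scc2-4, the direct comparison of the mutants, the genes with the smallest p were mostly near background. Of the 10, 7 were higher in sth1-3 and 3 lower, 8 were not above background in either mutant, and none passed the threshold (adjusted p = 1.00 for each). CRD1, the cardiolipin synthase, measured 9.75 ± 0.15 in sth1-3 and 8.70 ± 0.14 in scc2-4. YGP1, above background on 1 sth1-3 array, measured 9.96 ± 0.32 and 8.94 ± 0.00. INA1, MF(ALPHA)1, TVP38, BOR1 and VMA9 were the other higher ones. BCD1, an assembly factor of box C/D small nucleolar ribonucleoproteins, measured 8.85 ± 0.85 and 10.00 ± 0.08, and SLD2 of replication initiation and IFH1, a coactivator of ribosomal protein genes, were the other lower ones. At an unadjusted p under 0.05 there were 21 genes, and 227 with the set term, against 272 by chance. Each mutant has its arrays in different sets, which widens the spread in the fit without the term. With it 0 were called by limma, and without it 0 with any eBayes option. The arrays did not overlap in 984 genes (18.1%), against 33.3% by chance, which ignores that each mutant spans both sets. Ribosomal protein genes were the 1 list called, higher in sth1-3 (median 0.28, 99 of 127 members, adjusted p = 0.00526, and 0.996 with an estimated correlation). The median difference was 0.27 in the 3-array set and 0.32 in the 4-array set, each above all 10000 random lists matched on mean level. In both sets 67 members were higher, and 7 were lower in both. The random lists take no account of correlation between members, and each difference sets 1 array against 1. Neither the rank nor the member counts can therefore tell a difference between the mutants from a difference between arrays. The 25S 3' to 5' difference was wider in sth1-3 in both sets too, at 4.16 against 3.03 and 0.69 against 0.31, so the array signs move with the list. It changed sign when scc2-4 replicate 2 (-0.36) or sth1-3 replicate 1 (-0.36) was left out, which leaves the sets unbalanced.

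In wild type cells at 37C against 25C, the only array at 25C leaves that group without a replicate. Of the 10 genes with the smallest p, 8 were lower at 37C, and none passed the threshold (adjusted p = 0.449 for each). Ty1 and Ty2 reading frames were 5 of the 8: YDR261C-D at 7.49 ± 0.99 against 12.07 (at least 4.11-fold lower), YDR261W-B (at least 4.23-fold), YDR316W-B (at least 4.01-fold), YBL100W-B (at least 1.89-fold) and YAR010C (3.86-fold). UBP2, RIO1 and HUT1 were the other lower genes, and TRS31 and PKC1, the kinase of the cell wall integrity pathway, the higher ones, at levels not above background at either temperature. At an unadjusted p under 0.05 there were 555 genes, 177 higher and 378 lower, and 107 with the set term, against 272 by chance. Without the term 0 were called by limma with any eBayes option. Lower lists at 37C were ribosomal proteins (median -1.53, 120 of 127 members, adjusted p = 2.2e-15), glycolysis (-1.81, 15 of 16), Hsf1 heat shock chaperones (-0.98, 20 of 25, adjusted p = 0.00109), proteasome (-0.77) and ribosome biogenesis (-0.52). STI1, a co-chaperone of Hsp90, measured 10.29 ± 0.03 against 11.66. Higher lists were seripauperins (1.07, 16 of 19), alpha-specific genes (0.51), early meiosis (0.45), pheromone response (0.26) and G1/S genes (0.14). No member was called, over all genes or adjusted over the list alone, and no list was called with an estimated correlation (lowest adjusted p = 0.722).

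The array set and the temperature coincide in wild type, so this comparison also sets the 4-array set against 1 array of the other. With the set term, which rests on the mutants' arrays, 0 genes were higher and 4 lower, all Ty1 and Ty2 reading frames, and only the Hsf1 (-0.36, adjusted p = 0.0212) and alpha-specific lists (1.00, adjusted p = 2.7e-07) were called. With an estimated correlation neither was (lowest adjusted p = 0.975), and no alpha-specific gene was above background on a wild type array. A fit of the 3 wild type arrays alone called 911 genes, 291 higher and 620 lower. It takes its spread from the wild type 37C pair, whose arrays belong to 1 set, with 1 residual and infinite prior degrees of freedom. All genes then share 1 spread, and the 25C group has 1 array.

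Changes in the mutants against wild type at 37C correlated across the 5449 genes (Pearson r = 0.78, Spearman rho = 0.72), where genes are not independent replicates. Without scc2-4 replicate 1, r was 0.28. Unchanged groups simulated against the same wild type arrays gave r = 0.50. The covariance was 0.177, against a simulated 0.112. The simulated groups hold no array set effect, whereas both mutants span the sets alike. Values above the simulated ones therefore cannot be told apart from an effect of the sets. With the set term the observed r was 0.54 and the simulated 0.60, with covariances of 0.0634 and 0.0881. Within the 4-array set r was 0.58 against a simulated 0.34, with covariances of 0.0640 and 0.0547. The highest simulated values there were 0.39 for r and 0.0650 for the covariance, so the observed covariance was not above the simulated range. With a different wild type array for each mutant, so that no control is shared, r was 0.58 and 0.34 over all arrays, and 0.16 and 0.04 within the 4-array set. Part of the correlation without the split may come from the shared controls, and over all arrays the sets, which both mutants span alike, remain in the split too. Over all 7 arrays, no genes were called in either mutant by the model without a block or set term. With the set term, 7 and 9 genes were called higher, 7 in both, all Ty1 and Ty2 reading frames that are low on the wild type 37C arrays used in both comparisons.

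The relation of change to wild type level depended on the arrays. Over the 705 genes above background on the wild type 25C array, in 5 bins of 141, the median change of scc2-4 went from 0.03 in the dimmest bin to 0.50 in the brightest (rho = 0.263), and that of sth1-3 from 0.14 to 0.68 (rho = 0.275). In the brightest bin, scc2-4 replicate 1 had a median of 1.06 and replicate 2 of 0.00, and sth1-3 replicate 1 of 1.14 and replicate 2 of 0.20. The wild type 25C array belongs to the same set as replicate 1 of both mutants, and with replicate 2 alone rho was 0.0801 and 0.179. The direction depended on the array that sets the level: with the mean of the wild type 37C arrays rho was -0.712 and -0.763, where the level is also part of the change.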

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

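Signals outside the measured genes stood apart on replicate 1 of both mutants, in data that the comparisons do not use. The 3' probe set of 25S ribosomal RNA exceeded the 5' probe set by 3.03 on scc2-4 replicate 1 and by 4.16 on sth1-3 replicate 1, against 0.30 and 0.32 on the wild type 37C arrays. The bacterial hybridisation controls averaged 12.50 and 12.33 on these arrays, against 11.75 and 11.72. The wild type 25C array had values of 3.13 and 12.63.

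All tests of this grouping were chosen after it was seen. The gap between the sets of arrays in the 25S signal difference, 2.34, is larger than the range within either set, and bacterial controls are added to the sample and do not come from the cells, so a difference in the labelled material or its hybridisation is a candidate explanation. A missed shift to 37C in replicate 1 of the mutants was set against it with the Hsf1 chaperone list, which fell at the 0.17th percentile of 10000 lists matched on level for sth1-3 replicate 2 minus replicate 1, and at the 5.4th for scc2-4. The list was also lower in wild type at 37C than at 25C (-0.98), so it does not mark the temperature on these arrays. A missed shift adds no bacterial control signal, so it stays open only beside such a difference, not in its place. Temperature and array set coincide in wild type, and they cannot be told apart here.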

How the results depend on the processing

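Signal over background limits these data, since 4219 of 5449 genes lay above background on no array. Of the values that answer a comparison, 111 stayed within the spread or within 1.5 times the count without an alternative, 41 moved and 2 reversed. Some of the 111 could not move, such as the correlation of the mutants under the replicate block or under S. pombe centring. Others were gene counts of 0 in fits that find few changed genes, so the 111 is no measure of stability. Of the values for single genes and lists, 908 kept direction and side of the threshold, 90 lost a call, 47 gained one and 8 reversed. The single genes were the 10 with the smallest p in each comparison. None was called, and their arrays did not overlap between groups, so leaving out an array could not reverse them. For these genes the count is thus no measure of stability. Unless a cause is named, the cause was not tested. Centring on the S. pombe median moved the median of all genes from -0.01 to 0.12 in scc2-4, from 0.03 to 0.11 in sth1-3 and from -0.17 to -0.28 in wild type 37C against 25C, and no list called before lost its call or changed direction with it. Centring moves all genes of an array alike and camera sets a list against the other genes, so it could hardly alter these calls.

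Replicate differences correlated at -0.196 and -0.360 between wild type and the mutants and at 0.552 between the mutants. Both wild type 37C arrays lie in the 4-array set, while the replicates of each mutant lie in different sets. These correlations therefore cannot show whether the numbers pair wild type with the mutants. In both mutants, replicate 1 belongs to the 3-array set and replicate 2 to the 4-array set, so there the numbers follow the sets. With the replicate block 1 gene was called in scc2-4 and 1 in sth1-3 against wild type, YDR261C-D both times, and no list call was lost. With only genes above background on at least 2 arrays, 4, 4 and 5 lists were called in scc2-4, in sth1-3 and in wild type 37C against 25C, where fewer genes are tested, and the G1/S median of the last became -0.024. With only the 2 groups compared, 911 genes were called in wild type 37C against 25C (291 higher, 620 lower). With an estimated correlation 0 lists were called in each of the 4 comparisons, and with fry 0.

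With the array set term, added after the data were seen, 7, 10 and 4 genes and 0, 7 and 2 lists were called in scc2-4, sth1-3 and wild type 37C against 25C, and the proteasome median in scc2-4 became -0.025. Within the 4-array set, also added, 6, 13 and 1 genes and 1, 4 and 6 lists were called in scc2-4, sth1-3 and sth1-3 against scc2-4, and in scc2-4 the unfolded protein response median became -0.065 and that of the proteasome -0.011. The correlation of change with level fell to 0.0801 in scc2-4 and 0.179 in sth1-3. With the level from the wild type 37C arrays it was -0.712 and -0.763, where the arrays that set the level enter the change. The control split gave r = 0.344 for the mutants.

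With 1 array left out, the lone array of a group is assumed to vary like the others. Genes called ranged from 0 to 1 in scc2-4 and in wild type 37C against 25C. Lists called ranged from 1 to 12 in scc2-4, 5 to 15 in sth1-3, 1 to 7 in sth1-3 against scc2-4 and 9 to 12 in wild type. The correlation of the mutants ranged from 0.277 to 0.826, and that of change with level from 0.0801 to 0.279 in scc2-4 and 0.179 to 0.290 in sth1-3. In scc2-4, the unfolded protein response median ranged from -0.065 to 0.78 and the proteasome median from -0.011 to 0.56, both lowest without scc2-4 replicate 1. The ribosomal protein median of sth1-3 against scc2-4 ranged from -0.36 to 1.07.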

Other observations

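Ty1 and Ty2 reading frames, a list made after their values were seen, had a median of 11.49 on the wild type 25C array, 8.39 and 7.36 on the wild type 37C arrays, 11.90 and 9.93 on the scc2-4 arrays and 10.93 and 10.85 on the sth1-3 arrays. On every mutant array, 8 of 8 were higher than on both wild type 37C arrays. The 4 reading frames of Ty3 and Ty4, other families of retrotransposons, had median changes of -0.20 in scc2-4 and -0.01 in sth1-3, with 0 called. None was above background on any array, so they do not show whether these families changed. YLR154C-H, in the ribosomal DNA region, was called within the 4-array set in sth1-3 against scc2-4 (-2.34, adjusted p = 0.00295, limma), in a fit with 1 array per mutant. On the sth1-3 array of that fit the ribosomal RNA signals were low too, with 5.8S at 8.92 against 12.87 to 12.98 on the other 3 arrays and 18S at 12.34 against 13.03 to 13.79. The call is therefore not read as a change particular to this gene. YLR154C-H did not follow 5.8S on every array, since on the wild type 25C array 5.8S was at 8.40 and YLR154C-H at 11.52.

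All tests of the lower Ty1 and Ty2 signal on the wild type 37C arrays were chosen after it was seen. Within the 4-array set the smaller of the median changes was 2.03, on scc2-4 replicate 2, which argues against the array sets as the whole cause. On that array 4 of the 8 reading frames were above background. The change lay at the 100th percentile of 10000 lists matched on level. The list was made after its change was seen, so this rank alone settles nothing. The range of the matched lists was -0.18 to 0.20 on scc2-4 replicate 2. On sth1-3 replicate 2 it was -0.31 to 0.27, where the change of the 8 reading frames was 2.88. Compression of all probe sets at this level would move the matched lists too, so these values argue against it as the whole cause. They rest on 1 array per mutant, and compression particular to these probe sets, which share near-identical copies, stays open. Within the 3-array set the larger of the mutants' median differences from wild type at 25C was 0.074, but this sets 37C against 25C, so heat that lowers Ty RNA in every strain could hide more copies in the mutants. More Ty copies in the mutants, a different response of the strains to 37C, something particular to the wild type 37C arrays, and signal from several copies in the shared probe sets all stay open, since the mutants have no array at 25C.

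Ribosomal protein and glycolytic genes were higher on sth1-3 replicate 2 than on the wild type arrays of the same set (0.38 and 0.33). That array, whose 5.8S signal of 8.92 was near the 3-array set (7.50 to 8.40) though its bacterial controls (11.60) were not, may lie part of the way towards the other set, and this was tested by removing the trend on the difference between the scc2-4 replicates, with the test fixed before its result but after the list medians had been seen. The glycolysis median then was -0.022, inside the range of matched lists (-0.16 to 0.21), while the ribosomal protein median of 0.11 lay above theirs (-0.07 to 0.06), the outcome set beforehand as counting against the explanation. A second fit was added only after that result, because noise in the scc2-4 difference flattens an ordinary slope (0.242); total least squares (slope 0.315) left -0.0069, within -0.07 to 0.07, and glycolysis at -0.146, close to the lower limit of its range (-0.149). The ribosomal protein result thus depends on the slope chosen and cannot be told apart from a partial shift, and a change in sth1-3 cells stays open.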
